A study of Mus musculus with 12 samples.

How the data were processed

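RNA was measured in B16F10, an established mouse melanoma cell line that the labels describe as mouse melanoma cells. Per the labels, the cells grew in DMEM with 10% serum, total RNA was extracted with RNeasy Plus Mini columns, and libraries were made with the KAPA Stranded mRNA-Seq kit. The 12 libraries form 4 groups of 3: control (genotype given as wild type), Ep300 knockout, Crebbp knockout and knockout of both genes. The labels do not say whether the 3 libraries of a group are separate cultures, or whether each knockout is a clone or a pool. The p-values therefore measure only the spread between these samples, which may be technical.

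Per the labels, the authors made read files with bcl2fastq, aligned them with HISAT2 and counted them per gene with HTSeq on build mm10. Versions, the strand setting and the annotation release are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, with 1 column per library and no normalization, for 54752 genes. All 12 columns were used. A mouse annotation gave symbols, positions, exon lengths and GC content to 54723 of the genes. The other 29 held a share of counts of at most 0.0378 per mille in a library. Total counts ran from 64257251 in control replicate 2 to 85604243 in Ep300 knockout replicate 2.

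Genes with too few counts for the group size were removed with filterByExpr of edgeR, which left 18434 tested genes. Libraries were scaled by TMM (trimmed mean of M values). Changes were tested with the edgeR quasi-likelihood F test in its robust form. The fit used all 12 libraries, which share 1 estimate of the dispersion, with the group as the only term. The tested contrasts were each of 3 knockout groups against control, the 3 knockout groups against each other, and the double-knockout log2 change against the sum of both single-knockout log2 changes. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Errors beside log2 fold changes are standard errors derived from the F statistic, and n = 3 libraries per group throughout. CPM are read counts scaled to a common library total after TMM scaling, given as group means with the SD. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

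The gene lists, tests, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule named, for each knockout against control, Ep300, Crebbp, Mitf, Sox10, Myc, B2m and Cd274. It added the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM, with every library of 1 group beyond every library of the other, a condition that chance meets in 10% of genes. It also allowed the 2 members of each list with the smallest adjusted p under 0.05. The other comparisons named the 5 largest rises and falls, for the additivity test without the condition on libraries. Predicted, clone-named and mitochondrial genes were counted and not named individually. The largest rises, falls and differences given below for a comparison are ranked among the genes left by these conditions. Among genes picked by the rule or added later and called between 2 groups, all 185 calls had all 3 libraries beyond all 3 of the other group. The largest rises and falls had to meet this by the rule. Most others were picked by small adjusted p or after their values were seen, so the count is not independent support.

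The 22 lists covered melanocyte lineage and pigmentation, the dedifferentiated and invasive melanoma state, MHC class I antigen presentation, the interferon response, NF-kappaB targets and cytokines, hypoxia and HIF targets, p53 targets, CREB and cAMP targets, E2F targets and DNA replication, the G2/M phase, MYC targets and ribosome biogenesis, cholesterol synthesis and SREBP targets, the integrated stress response and ATF4 targets, extracellular matrix and TGF-beta response, acetyltransferases, deacetylases and coactivators, immune ligands and checkpoints of tumour cells, and neural crest and neuronal genes. Another 4 lists held markers of fibroblasts, immune cells, endothelium and epithelium, and 1 held histone genes without poly(A) tails as a sign of RNA quality. Each list was tested against all other genes with camera of limma at a preset correlation between genes of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and fry, which tests whether the members of a list move on balance 1 way, were alternatives.

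Responses of the knockout groups were compared by the correlation and covariance of log2 fold changes across genes and by the overlap of calls. Both were set beside 20 simulations of unchanged groups that share the controls. Alternatives were DESeq2, limma-voom, RLE size factors, no filter on low counts, a filter of 1 CPM in 3 libraries, only the groups compared, the replicate number as a block, and leaving out each library in turn. Offsets per library for exon length and GC content, and leaving out both libraries farthest along the length trend, were added after seeing the data.

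The tests were tried on simulated data with known changes. Of genes changed 1.5-fold, 62% were called with the right sign in a layout like the Ep300 comparison, 56% in one like the Crebbp comparison, 42% in one like the double comparison and 30% in the additivity test. Of genes changed 2-fold, 66% to 76% were called, and false calls made up 2.22% to 5.69% of calls. Camera called the changed list in all 3 layouts. In simulated data with a length trend, the offsets lowered the number of unchanged genes called from 1511 to 9 and kept 71.7% of changed genes called, against 75.9% without them. The rank correlation with exon length was 0.798 in that simulation and 0.253 in the real double-knockout comparison. The simulated trend had no GC part, and its changed genes were drawn without regard to length. It does not show what the offsets do to real changes that go with length.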

Results

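B16F10 mouse melanoma cells were profiled by RNA sequencing in 4 groups of 3 libraries: control, Ep300 knockout, Crebbp knockout and double knockout. Ep300 and Crebbp encode p300 and CBP, paralogous histone acetyltransferases that act as transcriptional coactivators. The design asks what the loss of each gene, and of both, does to transcript levels. Libraries held 64257251 to 85604243 counts, with group means of 73931666 ± 8542589 (SD, n = 3) in control, 80616394 ± 5224782 in Ep300 knockout, 71080171 ± 4077283 in Crebbp knockout and 81141151 ± 4956156 in double knockout. The biological coefficient of variation was 9.46%. The first principal component carried 51.1% of the variance and ordered the groups from control and Crebbp knockout through Ep300 knockout to double knockout.

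**Figure D1:**
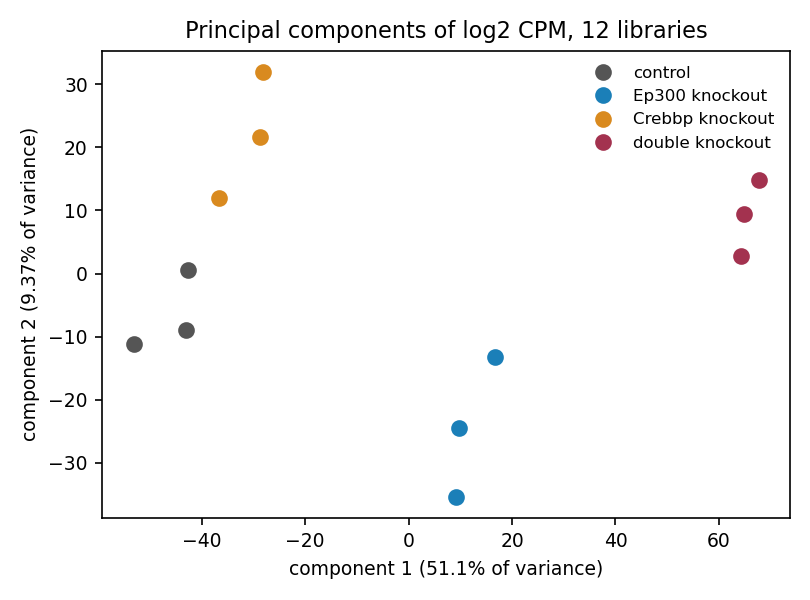
Principal components of log2 CPM for the 12 libraries, coloured by group, with component 1 (51.1% of the variance) on the x axis and component 2 (9.37%) on the y axis. The 3 double-knockout libraries lie at the right end of component 1, and the control and Crebbp-knockout libraries at the left.

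The targeted genes were read first. Crebbp (ENSMUSG00000022521, mm10 chromosome 16, 4081328 to 4213997, minus strand) stood at 64.7 ± 7.00 CPM in control (SD, n = 3), 34.5 ± 3.60 in Crebbp knockout, 80.7 ± 11.9 in Ep300 knockout and 64.0 ± 6.13 in double knockout. It fell in Crebbp knockout by 0.91 ± 0.12 on the log2 scale (adjusted p = 0.000527). Its log2 fold change was 0.32 ± 0.11 in Ep300 knockout (adjusted p = 0.0746) and -0.02 ± 0.11 in double knockout (adjusted p = 0.922). Ep300 (ENSMUSG00000055024, chromosome 15, 81585351 to 81652077, plus strand) stood at 94.4 ± 7.72 CPM in control, 85.1 ± 8.80 in Ep300 knockout, 104 ± 12.4 in Crebbp knockout and 148 ± 11.1 in double knockout. Its log2 fold change was -0.15 ± 0.10 in Ep300 knockout (adjusted p = 0.376) and 0.14 ± 0.10 in Crebbp knockout (adjusted p = 0.484), and it rose by 0.65 ± 0.10 in double knockout (adjusted p = 7.33e-05). With offsets for gene length and GC content, both transcripts are called lower where the plain fit made no call: Ep300 in Ep300 knockout at -0.19 ± 0.04 (adjusted p = 0.00206) and Crebbp in double knockout at -0.26 ± 0.05 (adjusted p = 0.00042). Crebbp in Ep300 knockout is then called higher at 0.27 ± 0.05 (adjusted p = 0.000886), and Ep300 in double knockout remains higher at 0.40 ± 0.04 (adjusted p = 4.07e-07). Each of the calls of a lower transcript came in 1 of 20 alternatives, these offsets, which were added after seeing the data. In double knockout the offsets lowered both targets, Ep300 from 0.65 to 0.40 and Crebbp from -0.02 to -0.26. The errors given with the offsets leave out the error of the offsets themselves. Gene-level counts do not show which exons are present, so transcript level alone does not measure loss of the protein, and the groups below are those of the labels.

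**Figure D2:**
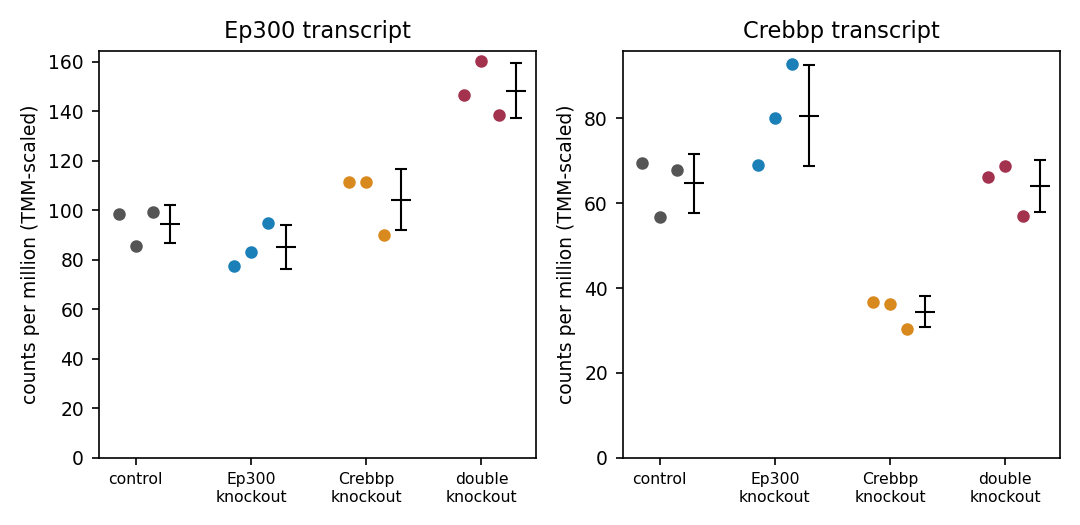
Ep300 and Crebbp transcripts in CPM (y axes, from 0) for each library by labelled group, with the mean and SD of 3 libraries beside the points. Crebbp is at 34.5 CPM in Crebbp knockout against 64.7 in control, and Ep300 is at 148 CPM in double knockout against 94.4 in control.

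In the libraries labelled Ep300 knockout, interferon-response genes rose, genes of antigen presentation rose, and genes of the melanocyte lineage fell. Isg15, a ubiquitin-like protein induced by interferon, rose from 10.1 to 85.4 CPM (log2 fold change 3.08 ± 0.07, n = 3, adjusted p = 1.64e-13). Kit, a receptor tyrosine kinase of the melanocyte lineage, fell from 12.9 to 1.36 CPM (-3.24 ± 0.11, adjusted p = 2.24e-11). Genes of cholesterol synthesis and of the integrated stress response were lower, by smaller amounts. In all, 2969 of 18434 tested genes changed, 1341 higher and 1628 lower, and 794 of these by at least 2-fold (405 higher, 389 lower).

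Of the 48 tested members of the interferon list, 46 rose in Ep300 knockout and the other 2 did not pass, over all genes and adjusted over the list alone. Their median log2 fold change was 1.88 (camera adjusted p = 2.21e-253). The largest rises of the comparison included Apol9a at 4.72 ± 0.09 and Apol9b at 4.50 ± 0.09, near-identical paralogs that share reads, Iigp1, an interferon-inducible GTPase, at 4.05 ± 0.23, and Oas2, an antiviral oligoadenylate synthetase, at 3.95 ± 0.26. In the list of MHC class I antigen presentation, 15 of 18 members rose and 3 did not pass, with 15 higher and 2 lower adjusted over the list alone (median 0.96, adjusted p = 2.93e-21). B2m, the light chain of class I molecules, rose from 322 to 594 CPM (0.88 ± 0.07), and the peptide transporter subunit Tap1 rose by 1.56 ± 0.11. Among immune ligands and checkpoints of tumour cells, 8 of 18 rose, also adjusted over the list alone, and 10 did not pass (median 0.33, adjusted p = 0.0014). Lgals9, which encodes galectin-9, rose by 1.34 ± 0.07, and Cd274, which encodes PD-L1, rose by 0.35 ± 0.09 (adjusted p = 0.0135). That call on Cd274 is lost without control replicate 1 (adjusted p = 0.0535), without Ep300-knockout replicate 3 (adjusted p = 0.0537) and with only the groups compared (adjusted p = 0.071). Cd68, a macrophage lysosomal marker on the immune list, rose from 1.87 to 3.47 CPM (0.90 ± 0.14), and the other 2 tested immune markers did not pass.

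Of 29 tested melanocyte genes, 22 fell in Ep300 knockout and 7 did not pass, with 25 lower adjusted over the list alone (median -0.48, adjusted p = 6.35e-24). Mitf, the master regulator of the lineage, fell from 925 to 668 CPM (-0.47 ± 0.07, adjusted p = 0.000201), and Mreg, a regulator of melanosome transport, fell by 1.22 ± 0.07 on the log2 scale. Sox10, which activates Mitf, was at -0.17 ± 0.10 (adjusted p = 0.306). In the dedifferentiated and invasive list, 16 of 24 rose and 4 fell, or 16 and 5 adjusted over the list alone (median 0.68, adjusted p = 2.72e-24). Ccn1, a matricellular protein and YAP target, rose by 2.34 ± 0.08, and Axl, a receptor tyrosine kinase, by 2.88 ± 0.11 (adjusted p = 4.6e-11). Sox9, a neural crest transcription factor and the largest fall in that list, was at -2.18 ± 0.15, and both Axl in this comparison and Sox9 were chosen after their values were seen. Of 17 neural crest and neuronal genes, 8 fell and 2 rose, also adjusted over the list alone (median -0.26, adjusted p = 6.46e-08), and S100b fell by 1.50 ± 0.08. The largest falls of the comparison included Cpne4 at -2.92 ± 0.09, the orphan receptor Gpr37 at -2.67 ± 0.10 and the peptide gene Cck at -2.35 ± 0.11.

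Of 31 cholesterol-synthesis genes, 21 fell and 10 did not pass, with 24 lower and 1 higher adjusted over the list alone (median -0.38, adjusted p = 2.2e-08). Sqle, squalene epoxidase, fell by 0.44 ± 0.06. Of 31 genes of the integrated stress response, 18 fell and 13 did not pass, with 23 lower adjusted over the list alone (median -0.31, adjusted p = 9.08e-10). The cystine transporter gene Slc7a11 fell by 1.48 ± 0.09. Of 29 CREB and cAMP targets, 13 rose and 5 fell, or 14 and 5 adjusted over the list alone (median 0.24, adjusted p = 0.00687, and 0.0778 as the adjusted p with an estimated correlation). Egr1, an immediate-early transcription factor, rose by 2.42 ± 0.12. Of 26 extracellular matrix genes, 11 rose and 6 fell, also adjusted over the list alone (median 0.15, adjusted p = 2.27e-05, and 0.226 as the adjusted p with an estimated correlation), with the protease inhibitor Timp1 at 2.19 ± 0.08 and Ltbp1, which binds latent TGF-beta, at 2.01 ± 0.09. Of 29 p53 targets, 2 rose and 7 fell, also adjusted over the list alone (median -0.18, adjusted p = 0.0177, and 0.0563 as the adjusted p with an estimated correlation), with Zmat3 at -0.95 ± 0.07 and Btg2 at 0.75 ± 0.07.

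The lists for NF-kappaB (6 of 19 rose and 3 fell, adjusted p = 0.119), hypoxia (3 of 33 and 6, 0.32), E2F targets (3 of 39 fell, 0.53), the G2/M phase (5 of 37 rose, 0.299), MYC targets (2 of 38 fell, 0.396), coactivators and acetylation enzymes (6 of 43 rose, 0.186) and histone genes without poly(A) (1 of 10 rose, 0.119) were not called as lists by camera in Ep300 knockout. Adjusted over the list alone, these counts were 8 and 3, 3 and 7, 3, 5, 2, 5 and 3. Of these lists, fry called NF-kappaB (adjusted p = 0.00391) and the G2/M phase (0.013) higher and hypoxia (0.00467) lower. Myc fell from 52.2 to 37.3 CPM (-0.49 ± 0.08, adjusted p = 0.000471). Except where a p with an estimated correlation is given, the list calls of the Ep300 comparison hold with it, at adjusted p between 4.83e-05 and 0.0301.

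In the libraries labelled Crebbp knockout, fewer genes changed and by smaller amounts. The 5 largest rises were Il11, a cytokine of the interleukin-6 family, at 1.95 ± 0.15, the small heat shock gene Hspb7 at 1.66 ± 0.20, Cyp26b1, which degrades retinoic acid, at 1.40 ± 0.12, and the collagen genes Col12a1 at 1.40 ± 0.16 and Col8a1 at 1.35 ± 0.08 (n = 3, adjusted p from 4.03e-07 to 0.000305). The 5 largest falls were Rapgef3, a cAMP-activated exchange factor, at -0.99 ± 0.09, Slc26a7 at -0.96 ± 0.15, the heparanase gene Hpse at -0.94 ± 0.09, Extl1 at -0.94 ± 0.11 and the syndecan gene Sdc3 at -0.91 ± 0.11. In all, 577 genes changed, 281 higher and 296 lower, and 91 by at least 2-fold (50 higher, 41 lower).

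Of 48 interferon-response genes, 21 rose in Crebbp knockout and 27 did not pass, with 30 higher adjusted over the list alone (median 0.35, adjusted p = 1.53e-29, and 0.0559 as the adjusted p with an estimated correlation). Isg15 rose from 10.1 to 18.1 CPM (0.84 ± 0.06, adjusted p = 1.57e-05), and Rtp4, another interferon-induced gene, rose by 0.81 ± 0.08. Of 29 melanocyte genes, 5 fell and 24 did not pass, with 11 lower and 1 higher adjusted over the list alone (median -0.13, adjusted p = 2.83e-05, and 0.0559 as the adjusted p with an estimated correlation). Oca2, a melanosomal transporter, fell by 0.85 ± 0.08, and Mitf was at -0.13 ± 0.07 (adjusted p = 0.347), Sox10 at 0.06 ± 0.10 (0.79) and Myc at 0.23 ± 0.08 (0.145). In the dedifferentiated and invasive list, 6 of 24 rose and 1 fell, or 9 and 2 adjusted over the list alone (median 0.12, adjusted p = 8.55e-07, and 0.34 as the adjusted p with an estimated correlation). Axl rose from 6.85 to 13.0 CPM (0.93 ± 0.11). Of 18 antigen presentation genes, B2m (0.31 ± 0.07, adjusted p = 0.031) and H2-K1, a class I heavy chain (0.33 ± 0.08, adjusted p = 0.0391), rose, and 5 rose adjusted over the list alone (median 0.11, adjusted p = 0.0158, and 0.128 as the adjusted p with an estimated correlation). Cd274 was at 0.24 ± 0.09 (adjusted p = 0.183).

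The calls on B2m and H2-K1 in Crebbp knockout lie near the threshold and end in 10 and 11 of 20 alternatives. B2m is not called without any 1 control (adjusted p = 0.0519, 0.0765 and 0.123 without replicates 1, 2 and 3), without Crebbp-knockout replicate 1 (0.111) or 2 (0.103), without double-knockout replicate 1 (0.0545) or 3 (0.0538), with only the groups compared (0.086), with the replicate number as a block (0.0762), or with the offsets (0.146). H2-K1 is not called without any 1 control (0.0533, 0.0679 and 0.178), without Crebbp-knockout replicate 1 (0.118) or 2 (0.166), without any 1 double-knockout library (0.0644, 0.0622 and 0.0627), by limma-voom (0.0654), with only the groups compared (0.122), or with the replicate number as a block (0.0736).

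Of 26 extracellular matrix genes, 5 rose in Crebbp knockout and 21 did not pass, with 6 higher and 3 lower adjusted over the list alone (median 0.06, adjusted p = 0.0457, and 0.65 as the adjusted p with an estimated correlation), with Ltbp1 at 1.04 ± 0.10 and Timp1 at 0.76 ± 0.08. Another 5 lists were called by camera with the preset correlation and not with an estimated one. These were the integrated stress response (3 of 31 fell, 0.0115, and 0.402 as the adjusted p with an estimated correlation), p53 targets (0.0405, and 0.176), the G2/M phase (1 of 37 rose, 0.0213, and 0.376), MYC targets (1 of 38 rose, 0.0158, and 0.34) and histone genes without poly(A) (3 of 10 rose, 0.0113, and 0.587). Adjusted over the list alone, these counts were 4 lower, 2 lower, 1 higher, 0 and 4 higher. No list was called in Crebbp knockout by camera with an estimated correlation. By fry, the integrated stress response (adjusted p = 0.0357) and p53 targets (0.00761) were lower, and the G2/M phase (0.0143) and MYC targets (0.0143) higher. Fry also called the interferon (0.00116), antigen presentation (0.00598) and dedifferentiated (0.0375) lists higher and the melanocyte list (0.000117) lower. Of 17 neural crest genes, 3 rose and 2 fell (adjusted p = 0.87), with S100b at -0.58 ± 0.08. Of 29 CREB targets, 2 rose and 2 fell (0.87), and Egr1 was among the higher at 1.16 ± 0.12. Of 33 hypoxia genes, 2 fell (0.844), Ndrg1 by -0.45 ± 0.09 among them, and of 18 immune ligands 1 rose and 1 fell (0.844), the latter being Lgals3, which encodes galectin-3, at -0.58 ± 0.08. In the NF-kappaB list 1 of 19 fell (0.844), and in the coactivator list 1 of 43 fell (0.137). Adjusted over the list alone, counts higher and lower were 3 and 2 for neural crest, 4 and 4 for CREB, 4 and 3 for hypoxia, 2 and 1 for immune ligands, 1 and 1 for NF-kappaB and 2 and 1 for coactivators. By edgeR, 0 of 31 cholesterol-synthesis genes, 0 of 39 E2F targets and 0 of 29 p53 targets passed, where 6, 4 and 7 had an unadjusted p under 0.05, and DESeq2 called 1, 3 and 4 and limma-voom 0 in each. The cholesterol-synthesis list was not called by camera (0.206) and was called lower by fry (0.0143).

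Several list calls in Crebbp knockout also end when 1 library is left out or in another setting. Antigen presentation is not called without control replicate 1 (adjusted p = 0.0637). MYC targets are not called without control replicate 1 (0.0637) or 3 (0.086), and the G2/M phase without control replicate 1 (0.0543) or 3 (0.0882) or Crebbp-knockout replicate 2 (0.0576). Histone genes without poly(A) are not called without control replicate 1 (0.0884) or Crebbp-knockout replicate 3 (0.482), or by fry (0.21). The p53 list is not called without control replicates 1 (0.0568) or 2 (0.142), Crebbp-knockout replicates 2 (0.0768) or 3 (0.0864), or double-knockout replicate 1 (0.0507), or with the replicate number as a block (0.0511). The extracellular matrix list is not called without control replicates 1 (0.0744) or 2 (0.486), Ep300-knockout replicate 1 (0.0606), Crebbp-knockout replicates 1 (0.213) or 2 (0.0984), or double-knockout replicates 1 (0.0516) or 2 (0.0553), nor with the block (0.0709), the offsets (0.265) or fry (0.339).

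The count of 577 genes in Crebbp knockout moved by more than 1.5 times in several settings. It was 365 without control replicate 1, 246 without control replicate 3, 299 without Crebbp-knockout replicate 1 and 214 without Crebbp-knockout replicate 2. It was 257 with only the groups compared, 321 with replicate numbers as a block, 1279 with DESeq2, 1270 with no filter on low counts and 1315 with the length and GC offsets.

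In the libraries labelled double knockout, each of the 48 tested interferon-response genes rose, 28 of 29 melanocyte genes fell, and cholesterol-synthesis genes were lower. Isg15 reached 255 CPM against 10.1 in control (4.65 ± 0.07, n = 3, adjusted p = 9.38e-16), and B2m reached 998 against 322 (1.63 ± 0.07). Mitf fell from 925 to 355 CPM (-1.38 ± 0.07, adjusted p = 4.93e-10), and Mc1r, the melanocortin receptor, from 87.4 to 22.7 (-1.95 ± 0.06). Axl rose from 6.85 to 171 CPM (4.65 ± 0.11, adjusted p = 1.02e-13). In all, 9102 genes changed, which is 49.4% of those tested, 4560 higher and 4542 lower, and 2395 by at least 2-fold (1244 higher, 1151 lower). The split into higher and lower depends on the scaling. The median log2 fold change over all tested genes was -0.016 with TMM and 0.071 with the length and GC offsets. A shift common to most genes would not show in these scaled counts.

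**Figure D3:**
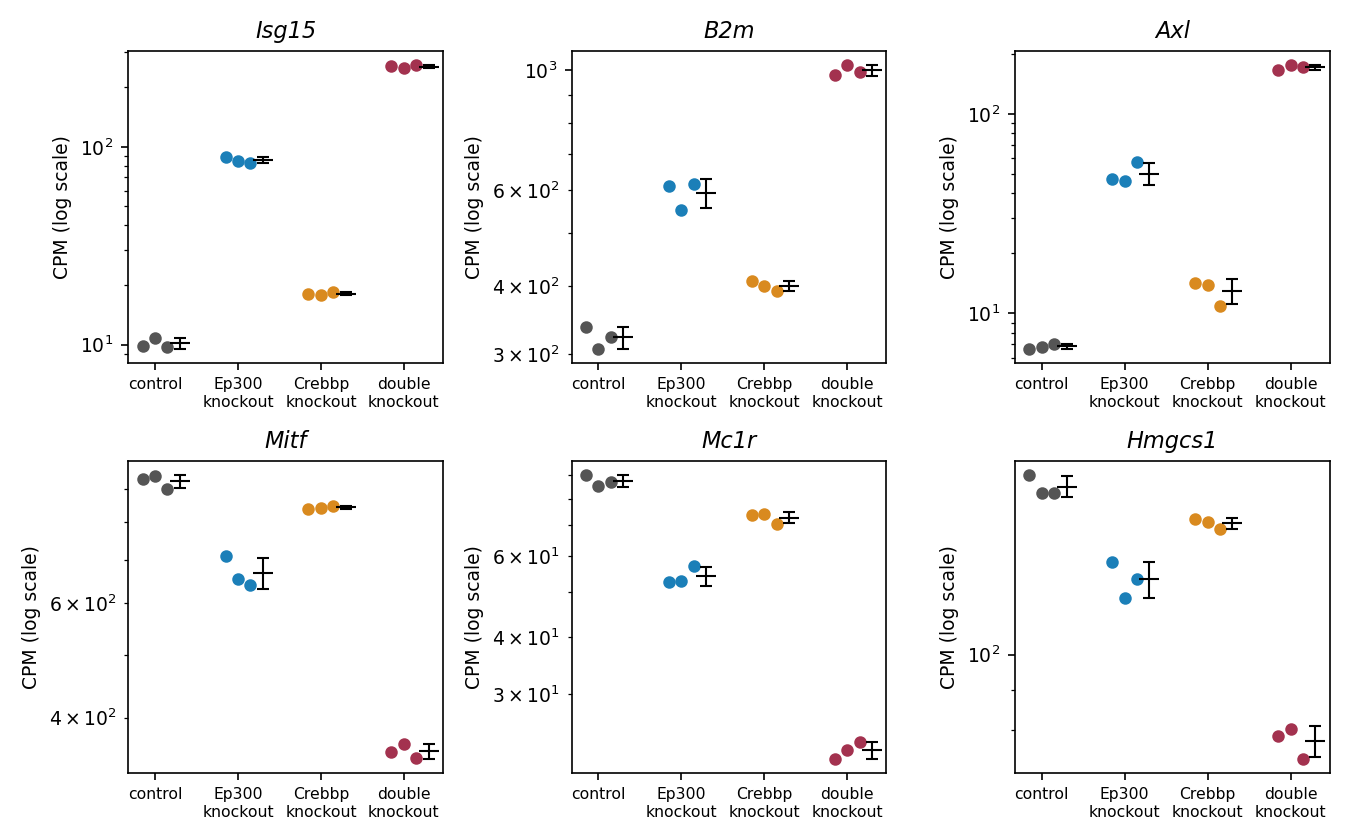
CPM on log axes for 6 genes in each library by labelled group, with the mean and SD of 3 libraries beside the points. Isg15, B2m and Axl are highest in double knockout (255, 998 and 171 CPM), and Mitf, Mc1r and Hmgcs1 are lowest there (355, 22.7 and 77.3 CPM).

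The median log2 fold change of the interferon list in double knockout was 3.33, with 48 higher also adjusted over the list alone (adjusted p = 9.78e-230). The 5 largest rises were Apol9a at 7.07 ± 0.09, Apol9b at 7.06 ± 0.09, Ifi44, an interferon-induced gene, at 7.04 ± 0.17, Il11 at 6.41 ± 0.14 and Oasl2, related to the oligoadenylate synthetases, at 6.39 ± 0.17. Of 18 antigen presentation genes, 15 rose and 3 fell, also adjusted over the list alone (median 1.91, adjusted p = 2.83e-22). H2-K1 rose by 2.28 ± 0.08 and Tapbp, which encodes tapasin, by 2.55 ± 0.09. The 3 that fell, chosen for naming after their values were seen, were the chaperones Calr at -0.80 ± 0.09 and Canx at -0.35 ± 0.07 and the disulfide isomerase Pdia3 at -0.75 ± 0.09, which serve general protein folding in the endoplasmic reticulum. Of 18 immune ligands, 9 rose and 5 fell, or 11 and 5 adjusted over the list alone (median 0.52, adjusted p = 0.00296), with Cd274 at 1.54 ± 0.09 and Lgals9 at 2.08 ± 0.07. Of 19 NF-kappaB targets and cytokines, 12 rose and 4 fell, also adjusted over the list alone (median 0.59, adjusted p = 0.00285, and 0.0803 as the adjusted p with an estimated correlation), with the cytokine genes Lif at 4.08 ± 0.20 and Csf1 at 2.21 ± 0.12. Of the immune markers, Cd68 rose to 6.18 CPM (1.73 ± 0.13) and the other 2 tested fell, and of the fibroblast markers both tested rose, Pdgfra from 1.39 to 4.57 CPM (1.70 ± 0.18). Of the 2 endothelial markers tested 1 fell, and the 1 epithelial marker tested fell. The 4 marker lists of other cell types were not called by camera in any of the 3 knockout groups against control, with adjusted p from 0.119 to 0.904. By fry, fibroblast markers were higher in Ep300 (adjusted p = 0.0208) and double knockout (3.61e-05), epithelial markers lower in both (0.00396 and 0.00158) and endothelial markers lower in double knockout (0.00967).

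The melanocyte list had a median of -1.41 in double knockout, with 28 lower also adjusted over the list alone (adjusted p = 2.23e-41). Mreg fell by 2.13 ± 0.07 on the log2 scale and Sox10 by 0.52 ± 0.10 (adjusted p = 0.000564). In the dedifferentiated and invasive list, 17 of 24 rose and 5 fell, also adjusted over the list alone (median 1.32, adjusted p = 6.26e-23). Ccn1 rose by 3.79 ± 0.08, and Sox9 at -1.62 ± 0.15 and Pdgfrb, a growth factor receptor chosen after its values were seen, at -0.88 ± 0.11 were among the falls. Of 17 neural crest and neuronal genes, 5 rose and 8 fell, or 6 and 8 adjusted over the list alone. Their median was 0.05 while their mean was -0.21 and camera called the list lower (adjusted p = 0.00412), with S100b at -2.24 ± 0.08. The 5 largest falls of the comparison were Ripor2 at -3.71 ± 0.16, Ccdc13 at -3.64 ± 0.17, Cpne4 at -3.46 ± 0.09, Cck at -3.34 ± 0.12 and Enpp2, which encodes autotaxin, at -3.34 ± 0.07.

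Of 31 cholesterol-synthesis genes, 28 fell in double knockout and 3 did not pass, also adjusted over the list alone (median -0.82, adjusted p = 2.16e-15). Insig1, a sterol sensor, fell by 1.40 ± 0.07 and Hmgcs1, HMG-CoA synthase, from 165 to 77.3 CPM (-1.09 ± 0.06). Of 29 CREB and cAMP targets, 19 rose and 6 fell, or 20 and 7 adjusted over the list alone (median 0.56, adjusted p = 1.56e-07), with Egr1 at 4.98 ± 0.12 and Atf3, a stress-induced transcription factor, at 2.13 ± 0.07. Of 26 extracellular matrix genes, 12 rose and 6 fell, or 12 and 7 adjusted over the list alone (median 0.32, adjusted p = 2.24e-05, and 0.223 as the adjusted p with an estimated correlation), with Ltbp1 at 4.37 ± 0.09 and Timp1 at 3.69 ± 0.08. Of 43 coactivators and acetylation enzymes, 23 rose and 7 fell, also adjusted over the list alone (median 0.28, adjusted p = 0.0074, and 0.333 as the adjusted p with an estimated correlation). Neither targeted gene is on that list. Brd2, a bromodomain protein that binds acetylated histones, rose from 184 to 452 CPM (1.30 ± 0.08). This call on the list is also lost with the length and GC offsets. Of 39 E2F targets, 23 fell and 1 rose, or 24 and 1 adjusted over the list alone (median -0.27, adjusted p = 0.00589, and 0.223 as the adjusted p with an estimated correlation).

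The remaining lists were not called as lists by camera in double knockout, while fry called hypoxia (adjusted p = 5.63e-06), the G2/M phase (0.000101) and MYC targets (0.000622) lower. In the integrated stress response 8 of 31 rose and 16 fell (median -0.20, camera adjusted p = 0.526), with Chac1, a glutathione-degrading enzyme, at 0.83 ± 0.08 and Slc7a11 at -0.85 ± 0.09. Counts higher and lower were 6 and 12 of 33 for hypoxia (0.11), 7 and 10 of 29 for p53 targets (0.874), 6 and 15 of 37 for the G2/M phase (0.149) and 5 and 14 of 38 for MYC targets (0.248), and 3 of 10 histone genes without poly(A) fell (0.52). These counts were unchanged when adjusted over the list alone. Ndrg1, a hypoxia-induced gene, fell by 2.15 ± 0.09, Plk2, a p53 target, rose by 1.25 ± 0.07, and Myc fell by 0.66 ± 0.08 (adjusted p = 7.89e-06). The list calls without a stated p for an estimated correlation hold with it, at adjusted p between 5.32e-05 and 0.0351. Double-knockout libraries differed from control in composition as well: mitochondrially encoded coding transcripts took 3.32% ± 0.297 of counts against 4.89% ± 0.473 (SD, n = 3), and coding genes with the symbol stems of ribosomal proteins 4.49% ± 0.296 against 5.98% ± 0.438. Across 8843 genes, which are not independent replicates, log2 fold changes in double knockout followed exon length with a rank correlation of 0.253, from a median of -0.21 in the shortest 20% of genes to 0.15 in the longest 20%.

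**Figure D4:**
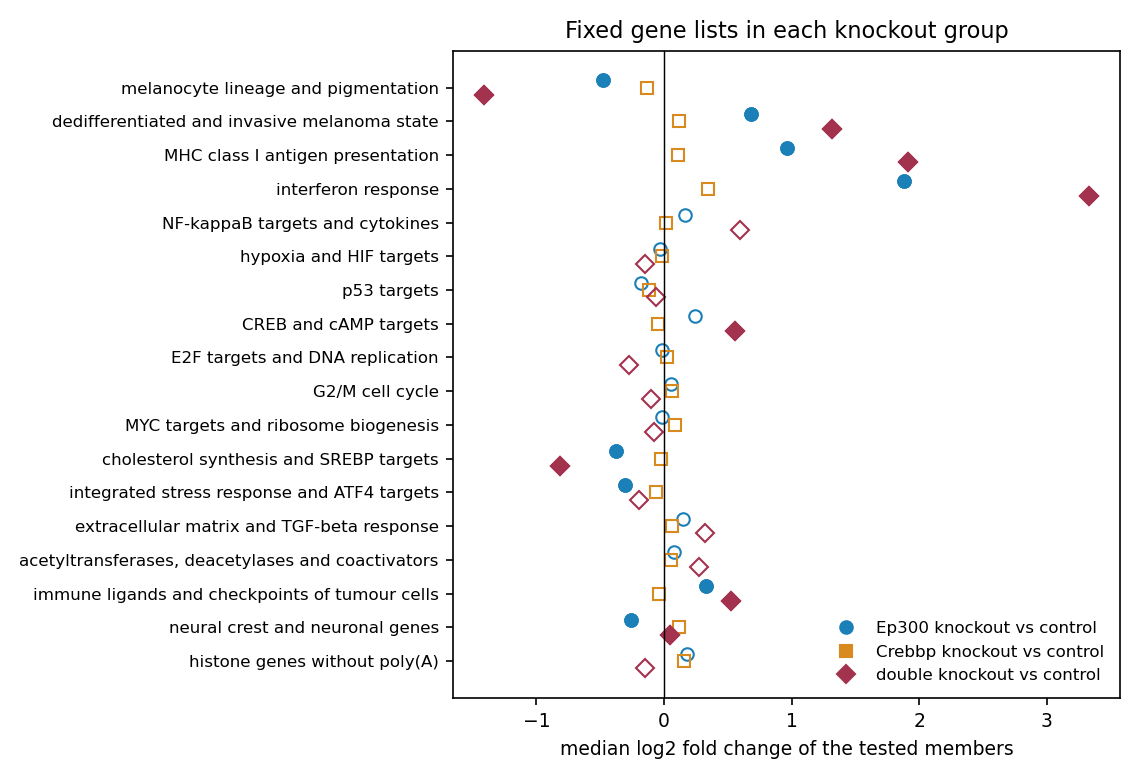
Median log2 fold change (x axis) of the tested members of 18 gene lists in each knockout group against control; filled symbols are lists called by camera with both the preset and the estimated correlation. The interferon list is at 1.88, 0.35 and 3.33 in Ep300, Crebbp and double knockout, and the melanocyte list at -0.48, -0.13 and -1.41.

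The direct comparison of the single knockouts asks whether loss of one paralog differs from loss of the other. Interferon-response genes were higher in Ep300 knockout than in Crebbp knockout for 46 of 48 members (median 1.52, adjusted p = 5.05e-227), and antigen presentation genes for 15 of 18 (median 0.85, adjusted p = 2.67e-19). Melanocyte genes were lower for 20 of 29 and higher for 2 (median -0.42, adjusted p = 6.96e-18), and cholesterol-synthesis genes lower for 19 of 31 (median -0.29, adjusted p = 7.38e-08). In all, 2512 genes differed, 1154 higher and 1358 lower in Ep300 knockout, and 620 by at least 2-fold (393 higher, 227 lower). The largest differences upward were Apol9a at 3.67 ± 0.08, Apol9b at 3.47 ± 0.08, the interferon-inducible genes Ifi211 at 3.40 ± 0.12 and Ifi204 at 3.38 ± 0.12, which are paralogs, and Iigp1 at 3.36 ± 0.21. The largest downward were Kit at -3.51 ± 0.11, Cck at -3.33 ± 0.11, Cyp26b1 at -3.20 ± 0.13, Gpr37 at -2.69 ± 0.10 and the gap junction gene Gjc3 at -2.39 ± 0.07. These 4 list calls hold with an estimated correlation, at adjusted p between 3.07e-05 and 0.000921.

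Double knockout was compared with each single knockout to ask what the second knockout added. Against Ep300 knockout, 45 of 48 interferon-response genes were higher (median 1.46, adjusted p = 4.51e-157), 24 of 29 melanocyte genes were lower and 1 higher (median -0.91, adjusted p = 6.77e-39), and 25 of 31 cholesterol-synthesis genes were lower (median -0.48, adjusted p = 6.76e-15). These calls hold with an estimated correlation, at adjusted p of 0.000111, 8.02e-05 and 0.000125. The integrated stress response, which was lower in Ep300 knockout, went the other way, with 17 of 31 higher and 2 lower than in Ep300 knockout (median 0.27, adjusted p = 5.89e-06, and 0.0865 as the adjusted p with an estimated correlation). In all, 6376 genes differed, 3315 higher and 3061 lower, and 902 by at least 2-fold (502 higher, 400 lower). The largest rises were Ifi44 at 3.29 ± 0.13, Oasl1 at 2.74 ± 0.09, Apol9b at 2.56 ± 0.07, Egr1 at 2.56 ± 0.11 and Oasl2 at 2.56 ± 0.13. The largest falls were the thyroglobulin gene Tg at -2.23 ± 0.09, Ccdc13 at -2.17 ± 0.17, the glutathione transferase paralogs Gsta1 at -2.09 ± 0.13 and Gsta2 at -2.03 ± 0.14, and Kank4 at -2.00 ± 0.12. Against Crebbp knockout, 48 of 48 interferon-response genes were higher (median 2.97, adjusted p = 5.79e-247), 26 of 29 melanocyte genes were lower (median -1.34, adjusted p = 1.24e-42) and 27 of 31 cholesterol-synthesis genes were lower (median -0.77, adjusted p = 4.65e-17), calls that hold with an estimated correlation. The integrated stress response had 10 higher and 12 lower there (adjusted p = 0.825). In all, 7966 genes differed, 3942 higher and 4024 lower, and 1881 by at least 2-fold (1062 higher, 819 lower). The largest rises there were Ifi44 at 6.58 ± 0.17, Apol9b at 6.03 ± 0.09, Apol9a at 6.02 ± 0.09, Oasl2 at 5.58 ± 0.16 and Iigp1 at 5.46 ± 0.20. The largest falls were Cck at -4.33 ± 0.12, Ccdc13 at -3.33 ± 0.17, Ripor2 at -3.09 ± 0.16, Enpp2 at -2.99 ± 0.07 and Kit at -2.85 ± 0.10.

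**Figure D5:**
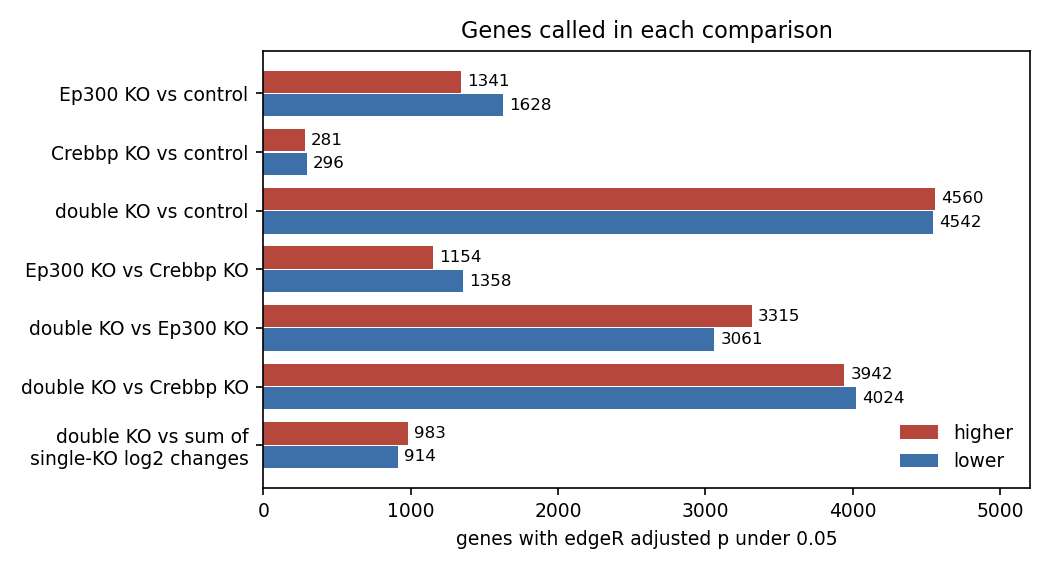
Number of genes with an edgeR adjusted p under 0.05 (x axis, from 0) in each comparison, split into higher and lower, out of 18434 tested genes. Bars run from 281 higher and 296 lower in Crebbp knockout to 4560 higher and 4542 lower in double knockout.

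The additivity test asked whether the log2 change in double knockout equals the sum of those in both single knockouts. Interferon-response genes rose beyond the sum for 40 of 48 members, or 43 adjusted over the list alone (median difference 1.02, adjusted p = 4.04e-91), and melanocyte genes lay below the sum for 21 of 29, or 23 below and 1 above adjusted over the list alone (median -0.68, adjusted p = 7.22e-35). Cholesterol-synthesis genes lay below the sum for 19 of 31, or 25 below and 1 above adjusted over the list alone (median -0.43, adjusted p = 4.01e-15). The 5 largest differences on each side were ranked among called genes with a mean of at least 5 CPM. Above the sum they were Ifi44 at 2.83 ± 0.26, the matricellular gene Ccn2 at 2.48 ± 0.14, Ifit3, an interferon-induced gene with a close paralog, at 2.09 ± 0.09, Oasl1 at 2.08 ± 0.15 and Lgr6 at 2.08 ± 0.23. The 5 largest below it were Kank4 at -2.19 ± 0.16, Cck at -1.98 ± 0.17, Ccdc13 at -1.86 ± 0.22, Tg at -1.74 ± 0.12 and Ttll11 at -1.71 ± 0.18. In all, 1897 genes lay off the sum, 983 above and 914 below, and 417 by at least 2-fold (238 above, 179 below). The 3 list calls hold with an estimated correlation, at adjusted p of 0.000415, 0.000123 and 0.000168. The count of 1897 was 1197 without control replicate 1, 2861 without control replicate 2, 1128 without control replicate 3, 1143 without Ep300-knockout replicate 2 and 1119 without double-knockout replicate 2, and 6 of 100 groupings of the libraries gave as many, the real one included.

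Across genes, which are not independent replicates, log2 fold changes in Ep300 and double knockout correlated with r = 0.820, in Ep300 and Crebbp knockout with r = 0.466, and in Crebbp and double knockout with r = 0.459. Simulated unchanged groups that share the same controls gave mean r of 0.525, 0.506 and 0.511. The covariances were 0.430, 0.110 and 0.171, against means of 0.0455, 0.0454 and 0.0453 in the simulations. Ep300 and double knockout shared 1266 genes called higher and 1466 called lower, where 331.7 and 401.1 would be shared if the calls were independent, and 15 genes were called in opposite directions. Ep300 and Crebbp knockout shared 145 higher and 195 lower (20.4 and 26.1 if independent) with 26 opposite, and Crebbp and double knockout shared 191 higher and 242 lower (69.5 and 72.9 if independent) with 29 opposite. The simulated unchanged groups shared 0 calls, so they set no level for overlap between groups that do change. By r, only Ep300 and double knockout lay above the simulations. All 3 covariances lay above them, and all same-direction overlaps lay above independence. With 3 controls, each comparison could not be given controls of its own, so part of these excesses may come from the shared controls.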

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

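The tests for immune cells, for interferon made by the cells, for exchanged labels and for each targeted transcript on its own were chosen after the result was seen, as were the offsets for gene length and GC content. The results in this part differ between groups: the log2 change in double knockout differed from the sum of the changes in both single knockouts, by a test of that difference. In all, 1897 genes did so. Of 100 groupings of the 12 libraries into 4 groups of 3, drawn with a fixed seed, 6 gave as many genes, the real one included, and the highest of the others gave 3994. The other groupings mix libraries of groups that differ, so their counts carry the differences between the knockout groups. The draw therefore cannot decide on chance, which is not excluded for this count. In 23 of the other groupings the 3 double-knockout libraries lay on the same side of the difference, and of these 5 gave as many genes as the real one, 1 gave fewer and 17 gave 0 by edgeR (544 to 5673 at an unadjusted p under 0.05). The 76 that parted those libraries gave 0 (at most 2455 unadjusted).

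For each of the other comparisons only 10 splits of 6 libraries exist, which is too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes. The real and highest other values were 2969 and 0 for Ep300 knockout, 577 and 0 for Crebbp knockout and 9102 and 0 for double knockout against control. They were 2512 and 606 for Ep300 against Crebbp knockout, 6376 and 0 for double against Ep300 knockout and 7966 and 0 for double against Crebbp knockout. At an unadjusted p under 0.05, edgeR counted 5005 and 3628, 3263 and 3553, 10136 and 566, 4700 and 4550, 8103 and 1819, and 9292 and 581 genes, in the same order. By that count, 1 other split of the Crebbp comparison exceeds the real one.

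Over all tested genes, 1897 of 18434 (10.3%) differed from the sum. The genes named in these texts were mostly picked for large changes or small adjusted p in these same data, some by this test. Their share is therefore not independent support. Of the 81 genes named in these texts and tested for additivity, 58 differed from the sum, 36 above and 22 below, with adjusted p from 2.13e-08 to 0.0364. The log2 differences above the sum were Lif 3.07, Ifi44 2.83, Ccn2 2.48, Ifit3 2.09, Oasl1 2.08, Lgr6 2.08, Zbp1 1.91, Ifi204 1.81, Atf3 1.81, Oasl2 1.75, Apol9b 1.53, Iigp1 1.41, Egr1 1.41, Ltbp1 1.33, Apol9a 1.30, Plk2 1.13, Slc7a11 1.10, Ifi211 1.09, H2-K1 1.06, Tap1 0.99, Cd68 0.99, Ccn1 0.98, Csf1 0.98, Cd274 0.95, Btg2 0.93, Tapbp 0.90, Axl 0.84, Timp1 0.75, Isg15 0.74, Chac1 0.71, Ep300 0.66, Adar 0.62, Brd2 0.59, Crebbp 0.57, Lgals9 0.51 and B2m 0.44. Those below it were Kank4 -2.19, Cck -1.98, Ccdc13 -1.86, Tg -1.74, Ttll11 -1.71, Gsta1 -1.51, Gsta2 -1.34, Ripor2 -1.16, Col12a1 -1.08, Mc1r -0.99, Insig1 -0.93, Col8a1 -0.90, Cyp26b1 -0.90, Oca2 -0.88, Pdgfrb -0.85, Mitf -0.78, Enpp2 -0.76, Calr -0.60, Ndrg1 -0.60, Mreg -0.56, Hmgcs1 -0.54 and Myc -0.40.

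For 53 of these 58 genes the call held without each library in turn. Zbp1 lost it without control replicate 3 (adjusted p = 0.113), B2m without Ep300-knockout replicate 2 (0.0507) and Iigp1 without control replicates 1 (0.111) or 3 (0.0514). Crebbp lost it, at adjusted p from 0.0704 to 0.0938, without control replicates 1 or 3, Ep300-knockout replicates 1 or 2, Crebbp-knockout replicate 3, or double-knockout replicates 1 or 2. Myc lost it, at adjusted p from 0.0557 to 0.0845, without control replicate 1, Ep300-knockout replicates 2 or 3, Crebbp-knockout replicates 1 or 2, or any 1 double-knockout library.

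Of the gene lists, 17 differed from the sum, 10 above and 7 below. Median differences above it were 1.02 for the interferon response, 0.76 for antigen presentation, 0.43 for the dedifferentiated and invasive state, 0.43 for CREB targets, 0.32 for the integrated stress response, 0.22 for NF-kappaB targets, 0.20 for immune ligands, 0.17 for extracellular matrix, 0.17 for acetylation enzymes and coactivators and 0.15 for p53 targets. Those below it were -0.68 for melanocyte genes, -0.55 for histone genes without poly(A), -0.43 for cholesterol synthesis, -0.27 for the G2/M phase, -0.25 for E2F targets, -0.17 for hypoxia and -0.15 for MYC targets. With an estimated correlation between genes, 7 of these calls are lost: dedifferentiated state (adjusted p = 0.149), hypoxia (0.092), MYC targets (0.13), extracellular matrix (0.418), coactivators (0.312), immune ligands (0.0593) and histone genes (0.151). The extracellular matrix call is also lost with the length and GC offsets (0.3), by fry (0.086), and without control replicate 3 (0.0621), Ep300-knockout replicate 1 (0.0525) or 2 (0.0627) or Crebbp-knockout replicate 3 (0.105), and the coactivator call with the offsets (0.117).

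The interferon-response list had a median log2 fold change of 3.33 in double knockout (n = 3). With the length and GC offsets the median was 3.42 and 48 of 48 members were called higher, which argues against that trend as the cause. Immune cells in the cultures would bring their abundant transcripts, yet the median of the 14 fixed immune markers, 3 of which these cells express at a testable level, was 0.00618 CPM (here without TMM scaling) in double knockout, with 13 below 1 CPM and at most 1 count of Ptprc, 5 of Laptm5 and 0 of Tyrobp in any library. Interferon made by the cells stays open, as Ifnb1, the interferon beta gene, rose by 4.72 ± 0.45 (adjusted p = 5.52e-07), a transcript rise that does not tell whether the interferon acted on the list or is part of the same response. The loss of p300 and CBP that the labels give, acting on these genes without interferon, also stays open and was not tested, as does a difference between the cell populations compared.

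In double knockout against control, Ep300 was at 0.65 ± 0.10 and Crebbp at -0.02 ± 0.11, so neither targeted transcript was called lower (n = 3). A test of the length and GC trend on both transcripts together, set beforehand, was met by Crebbp alone, and the transcripts were therefore separated afterwards. Ep300 stayed at 0.40 ± 0.04 with the offsets, which argues against the trend as its whole cause, while Crebbp moved to -0.26 ± 0.05 (adjusted p = 0.00042), so the trend may account for part of its level. Of 24 ways of assigning the 4 labels to the groups, the deposited one included, 0 made both transcripts lower wherever they are targeted, so that test does not separate the deposited labels from exchanged ones, which stay open. Edits that remove the protein and keep the transcript, and cells that escaped the edit, also stay open and were not tested, since gene-level counts do not show which exons are present.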

How the results depend on the processing

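The offsets for gene length and GC content, and leaving out both libraries farthest along the length trend, were chosen after seeing the data, and the other alternatives were planned. Under the alternatives run for them, no gene list and no named gene turned in direction where either fit called it. Named genes without a call in both fits could change sign, such as Sox10 in Crebbp knockout, from -0.04 to 0.13. Gene counts and correlations were judged by size alone, which leaves out the balance of higher and lower genes. Gene families, which were not run without each library, are given with the other observations. The number of genes changed in Crebbp knockout, 577, was 1279 with DESeq2, 1270 with no filter on low counts, 1315 with the offsets, 257 with only the groups compared and 321 with the replicate number as a block. The block changes the model and only the groups compared uses 6 of the 12 libraries, and beyond that the cause was not tested. Without each library in turn it ran from 214 (without Crebbp-knockout replicate 2) to 774 (without Ep300-knockout replicate 3), and the 1897 genes off additivity ran from 1119 (without double-knockout replicate 2) to 2861 (without control replicate 2). Leaving out a library changes both the spread and the number of libraries, and the cause was not tested. The counts of the other 5 comparisons stayed within 1.5 times of their values under every alternative run. Without both far libraries (control replicate 2 and Crebbp-knockout replicate 3) the counts were 3224, 412 and 8763 for Ep300, Crebbp and double knockout against control, 3048, 7520 and 7381 between the knockout groups and 2388 off additivity. Of 154 list tests, 91 were called, against 46 with an estimated correlation between genes (the cause was not tested), 115 by fry, 90 with the block, 86 with the offsets and 86 to 91 without each library. The correlation across genes was 0.466 for Ep300 and Crebbp knockout, 0.820 for Ep300 and double and 0.459 for Crebbp and double. With a filter of 1 CPM in 3 libraries it was 0.515, 0.878 and 0.524, where fewer genes with low counts enter, and without each library it ran from 0.409 to 0.536, 0.760 to 0.827 and 0.379 to 0.506. Among named genes, calls were lost and gained in 87 and 5 tests without a library, 4 and 7 with the offsets, 2 and 1 with limma-voom, 1 and 3 with no filter on low counts, 18 and 0 with only the groups compared, 9 and 0 with the block, 0 and 4 with DESeq2 and 0 and 1 with the filter of 1 CPM, and none changed with RLE size factors. Genes that a filter removed have no value under it. The replicate numbers do not pair the libraries: of 18 pairs with the same number in different groups, 6 had a residual correlation over 0.1 and 12 one below -0.1, from -0.74 to 0.67, and 4 of 12 libraries correlated best with their own number. Libraries held at least 64257251 counts, and a gene near the floor such as Ifnb1, with 1 to 2 counts per control library, keeps a wide error.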

Other observations

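The tests on gene families, Ifnb1, Zbp1 and Adar were chosen after the result was seen. The bounds of both tests on mitochondrially encoded transcripts were set before those tests were run. The length and GC offsets, which 1 of them uses, were added after seeing the data. Families of at least 10 tested coding genes that share the stem of their symbol, 161 in all, were tested with camera against all other genes. Of the Ifi genes, which are interferon-induced, 10 of 10 rose in Ep300 knockout (median 3.00, adjusted p = 3.6e-59, and 0.00163 with an estimated correlation) and in double knockout (median 4.55, adjusted p = 1.04e-40, and 0.00615). Of 12 Parp genes 6 rose in Ep300 knockout, and 9 rose and 2 fell in double knockout (medians 0.59 and 1.41, and 0.0649 and 0.0556 with an estimated correlation). Of 11 Irf genes 6 and 8 rose (medians 0.32 and 0.51, and 0.0649 and 0.0556), and of 49 Trim genes 17 rose and 5 fell in Ep300 knockout and 30 rose and 4 fell in double knockout (medians 0.16 and 0.48, and 0.282 and 0.21). These medians keep their sign with RLE size factors, DESeq2, limma-voom and the length and GC offsets.

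Zbp1, a sensor of Z-form nucleic acids, went from 0.191 CPM in control to 1.65 in Ep300 knockout (3.10 ± 0.28, n = 3, adjusted p = 9.87e-07) and 10.8 in double knockout (5.82 ± 0.25, adjusted p = 5.73e-11), and was at 0.338 in Crebbp knockout (0.81 ± 0.36, adjusted p = 0.261). Adar, which edits double-stranded RNA, went from 29.8 CPM to 67.8 in Ep300 knockout (1.18 ± 0.08, adjusted p = 4.16e-08) and 131 in double knockout (2.13 ± 0.08, adjusted p = 1.59e-11). In Crebbp knockout Adar was at 37.4 CPM (0.33 ± 0.08, adjusted p = 0.0401). That call is lost without any 1 control (adjusted p = 0.0727, 0.102 and 0.12 for replicates 1, 2 and 3), without Ep300-knockout replicate 2 (0.0595), without Crebbp-knockout replicates 1 (0.154) or 2 (0.142) and without any 1 double-knockout library (0.0639, 0.0574 and 0.0533). It is also lost with limma-voom (0.0515), only the groups compared (0.0945) and the replicate number as a block (0.0957).

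Ifnb1 had 1 to 2 counts per control library, 1 to 2 per Crebbp-knockout library, 12 to 19 per Ep300-knockout library and 41 to 56 per double-knockout library. Its log2 fold changes were 3.20 ± 0.50 (adjusted p = 0.000298) in Ep300 knockout, 0.02 ± 0.75 (adjusted p = 0.993) in Crebbp knockout and 4.72 ± 0.45 (adjusted p = 5.52e-07) in double knockout, and its difference from additivity was 1.50 ± 0.87 (adjusted p = 0.385). With 4 counts over the control libraries, the ratio to control and its counting interval were 9.90 (3.61 to 37.9) in Ep300 knockout and 28.6 (10.9 to 106) in double knockout. Of 21 interferon ligand genes, 1 had enough counts to be tested and 2 reached 10 counts in a library.

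In double knockout, 13 of 13 mitochondrially encoded coding transcripts were called lower, with a median log2 fold change of -0.69 (-1.49 to -0.56). With the length and GC offsets the median was -0.25 (-0.82 to 0.06) and 6 were called. The median fall became smaller, and whether wider errors also ended calls was not examined. Of 36 nuclear coding genes as short and as abundant, 36.1% lay at or below the mitochondrial median and their own median was -0.64. The mitochondrial fall was therefore not set apart from that of these genes. The 36 genes were not examined by family. A fall of short abundant transcripts in general thus cannot be told from a fall of 1 family among them. The part left after the offsets lies between the bounds set beforehand and stays open, as does a change in mitochondrial transcription, and no biological explanation was tested.

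Genes with the symbol stems of ribosomal proteins fell in double knockout: 45 of 49 Rpl genes (median -0.60, and -0.35 with the offsets) and 33 of 44 Rps genes, with 6 higher (median -0.63, and -0.34). Of 48 genes with the mitochondrial ribosomal stem Mrpl, 29 fell and 2 rose (median -0.36, and -0.21). These families rest on the symbol alone and may hold genes that do not encode ribosomal proteins. With an estimated correlation the adjusted p was 0.923 for each. Of 59 Hist genes, 13 rose in Ep300 knockout and 9 in Crebbp knockout (medians 0.20 and 0.23, also with the offsets), while in double knockout 6 rose and 25 fell, at a median of -0.25 that turns to 0.08 with the offsets. Of these genes 40 lay below additivity and 2 above (median -0.69, and -0.34 with the offsets), and with an estimated correlation the adjusted p was 0.983, 0.974, 0.924 and 0.562 in these 4 comparisons. The 7SK transcript Rn7sk took 3.59% ± 0.381 of counts in control and 2.75% ± 0.248 in double knockout (SD, n = 3), and the mitochondrial share was 4.78% ± 0.440 in Ep300 knockout and 4.87% ± 1.29 in Crebbp knockout. TMM factors averaged 0.943 ± 0.0471 in control and 1.11 ± 0.0108 in double knockout. Rank correlations of log2 fold change with exon length were 0.0464 in Ep300 knockout, 0.124 in Crebbp knockout, 0.338 between double and Ep300 knockout, and 0.346 in the additivity test.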
